A study of Xenopus laevis with 6 samples.

How the data were processed

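Testes of Xenopus laevis were compared between 3 libraries of animals exposed to atrazine and 3 libraries of unexposed controls. Group and replicate number came from the sample titles, and dose, duration and stage from the labels. Per the labels' protocols, testes were flash-frozen, RNA was taken with Trizol, and stranded libraries were made from rRNA-depleted total RNA. Per the submitters' processing notes the tools named were CASAVA 1.8, Bowtie2 and HISAT2, with no role or order. The quantifier, the circRNA caller, the annotation release and the genome build are not given in the sources used here. Coordinates are those of the files, written from 1, and chromosome names were read from the chromosome column of the mRNA table.

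Of the deposited tables, 2 hold FPKM values per mRNA gene (31598 rows) and per lncRNA transcript (4652 rows), per the file headers. FPKM divides reads by transcript length and library size, so short transcripts can reach a high FPKM from few reads. Beside them the authors deposited a signal per row that is headed as counts but is not whole. Nearly all its values in the mRNA table are whole multiples of 1 step per library, 99.77% or more of them in each library at a tolerance of 0.02, which looks like reads divided by a factor per library, although a few rows hold values too small for this. The depth of the mRNA table was estimated from that step, and no count model was run on the values. The smallest library, atrazine replicate 3, has an estimated 7360619 reads, and there 1 FPKM stands for a median of 16.7 reads against 38.2 in control replicate 1, so low rows are less precise in it. The third deposited table holds 68575 circRNAs with raw back-splice junction counts and log2 normalized values, per the file headers. No cell of the counts equals 1 and the smallest count above 0 is 2, so single reads were removed before deposit. The deposited log2 values equal the log2 of the count, with 0 taken as 1, plus 1 constant per library. The control columns of the circRNA table carry a shorter name than the sample labels and were matched to them by their number. Depth sets the counting error only, and PCR copies among the reads cannot be told from separate molecules.

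Of the mRNA rows 20208 (64.0%) are named only by a LOC number, and 11219 of them have a symbol in the annotation of assembly v10.1, which was used for names and for 1 alternative, never for coordinates. L and S copies of a gene can share reads, and the authors' treatment of such reads is not given in the sources used here. The labels say that the kit keeps strand, and whether the counting used it is not given in the sources used here.

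mRNAs and lncRNAs were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(FPKM + 1), on rows with at least 0.5 FPKM in at least 3 libraries. circRNAs were tested with the quasi-likelihood test of edgeR 4.0.16 on the junction counts with TMM factors, on rows with at least 2 reads in at least 3 libraries. All tests were two-sided, with Benjamini-Hochberg adjustment within a table and a threshold of 0.05, and group was the only term. Numbers of detected circRNAs were compared with an exact permutation test of the difference of group means, which has 20 assignments and a smallest p of 0.1. The 27 gene lists, with at least 5 measured rows each, were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. A row belonged to a list when its deposited symbol without L or S matched. The lists covered germ cell stages, testis somatic cells, steroid and cholesterol synthesis, receptors, ovary, detoxification, stress, energy metabolism, cell cycle, repair and other tissues that a dissected testis could hold. The circRNA and host gene fold changes were correlated across circRNAs.

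The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 called mRNAs in each direction with a symbol, without overlap between groups and with a mean of at least 1 FPKM. As none was called, it took the 5 with the smallest p in each direction, said not to pass. It further took up to 4 symbols of each list, some of which are not reported here, 10 genes of steroid and sex biology, and, with none called, 2 lncRNAs and 3 circRNAs in each direction. The tests met the units as planned for each kind of table.

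The scripts were tested on simulated data with 200 changed rows per draw and 5 draws, made from the rows' own means and the libraries' sizes. For mRNAs (23564 rows tested on average) 80.7% of 2-fold decreases, 81.5% of 2-fold increases and 27.1% of 1.5-fold increases were recovered, with 12.8 false calls per draw. That simulation gave all rows 1 coefficient of variation of 0.131, the median of rows with a high mean signal, and let rows vary independently. Real rows differ in spread and vary together, so recovery in the real data can be lower. For lncRNAs (1796 rows) 14.5% of 2-fold decreases and 18.7% of 2-fold increases were recovered, and 59.5% of 4-fold decreases and 87.5% of 4-fold increases. For circRNAs (4317 rows), at the coefficient of variation of 0.863 that edgeR estimated, 1 of 155 circRNAs raised 8-fold was recovered and none of the other changed ones. A list of 55 rows shifted by 0.3 on the log2 scale was called in 5 of 5 draws, and 0 of 130 unshifted lists were called, with simulated rows varying independently.

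Alternatives were another pseudocount (0.1), no filter and a stricter filter, median-of-ratios and quantile scaling, no variance trend, an unadjusted threshold with a 2-fold change, the replicate number as a block, leaving out each library, and, for circRNAs, DESeq2 1.42.0, no TMM, no filter, a minimum of 5 reads and thinned reads. Chosen after the data were seen were library weights, the scaled signal in place of FPKM, circRNA library sizes from the mRNA table, limma on the deposited log2 circRNA values, current symbols for lists, a wider Leydig list (whose added rows were picked for their values, so that its test is not read), a minimum of 2 reads after thinning, and totals matched after that minimum. All pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 7.17 or more, so none was counted as a repeat.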

Results

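Testes of the African clawed frog Xenopus laevis, an allotetraploid whose paired chromosome sets carry the suffixes L and S in gene symbols, were profiled after long exposure to atrazine, a triazine herbicide. The 3 tables came from rRNA-depleted stranded total RNA libraries and covered mRNAs, long non-coding RNAs (lncRNAs) and circular RNAs (circRNAs), which are closed RNA rings read through their back-splice junctions. The atrazine group had been kept at 100 µg/L for 180 days and the control group had not been exposed. Both groups held 3 libraries, taken at postnatal day 193. Estimated from the value that 1 read takes in each library, the mRNA table rested on 14549422, 15393416 and 7360619 reads in atrazine replicates 1, 2 and 3, and on 17018690, 16841759 and 13784625 reads in control replicates 1, 2 and 3. Junction reads numbered 63622, 52138 and 37092 in the atrazine libraries and 69338, 86265 and 61193 in the control libraries. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries. Fold changes of mRNAs and lncRNAs are on the log2(FPKM + 1) scale, atrazine minus control, which understates changes of low rows.

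The first comparison asked which mRNAs differed between exposed and control testes. The mRNAs with the smallest p included a sperm nuclear protein and products of the hormone-making Leydig cells. The gene sp4-c, which encodes a sperm-specific basic nuclear protein, stood at 329 ± 36.0 FPKM in atrazine testes and 925 ± 254 FPKM in controls (SD, n = 3), 2.75-fold lower after exposure. The 2 rows described in the deposited table as insulin-like 3, a peptide hormone of Leydig cells, were 3.95-fold and 3.63-fold lower. No mRNA passed the threshold, however, since 0 of 23824 rows reached an adjusted p below 0.05 with limma and Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.110. At an unadjusted p under 0.05 limma gave 1410 mRNAs, 792 of them higher and 618 lower in atrazine. The values of the groups did not overlap in 11.3% of rows, against the 10% that chance gives for 3 libraries against 3. Leaving out control replicate 1 gave 5 called mRNAs and 4498 at an unadjusted p under 0.05, and leaving out atrazine replicate 3 gave 1 called mRNA. At an unadjusted p under 0.05 there were 657 mRNAs without atrazine replicate 2, 781 without control replicate 2 and 779 without control replicate 3.

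None of the named mRNAs below passed the test over all rows. Among rows with a gene symbol (not a LOC or MGC number) and no overlap between the groups, the higher ones with the smallest p were cnn1.L, lef1, chchd5.L, g67.L and nup205.L, with log2 fold changes of 0.60, 0.71, 0.76, 0.87 and 0.69. The calponin gene deposited as cnn1.L, named cnn2.L in assembly v10.1, had means of 13.7 ± 0.466 FPKM in atrazine and 8.74 ± 0.293 FPKM in control (SD, n = 3). The transcription factor gene lef1, a partner of beta-catenin in Wnt signalling, had means of 7.78 ± 0.800 FPKM in atrazine and 4.36 ± 0.421 FPKM in control (SD, n = 3). The row of the nuclear pore gene nup205.L, nup205.S in assembly v10.1, had means of 18.5 ± 1.77 and 11.2 ± 2.00 FPKM. Its identifier is nup205.L_2 and it lies at 148 to 506 of an unplaced sequence, so it may hold only a part of the gene. The lower ones with the smallest p under the same limits were sp4-c, fbp1.S, rtbdn.L, kiaa0930.L and hsd3b1.L, with log2 fold changes of -1.46, -0.75, -0.69, -0.65 and -0.72. Of these the kiaa0930.L row, kiaa0930.L_2, lies at 81 to 586 of an unplaced sequence and may likewise hold only a part of its gene. Fructose-bisphosphatase, the gluconeogenic enzyme encoded by fbp1.S, had means of 13.6 ± 0.692 FPKM in atrazine and 23.7 ± 3.07 FPKM in control (SD, n = 3). The limma adjusted p was 0.406 for sp4-c and 0.693 for the other named mRNAs of this group.

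Steroid hormone synthesis was examined with a list of Leydig cell and steroid genes, of which 18 rows were higher and 19 lower among 37 measured. Adjusted over all genes tested none of them passed in limma, and adjusted over the list alone 2 did, star and hsd3b1.L, both with an adjusted p of 0.0285. The gene star encodes the protein that carries cholesterol into mitochondria, the rate-limiting step of steroid synthesis. It stood at 33.6 ± 12.3 FPKM in atrazine and 66.8 ± 5.31 FPKM in control (SD, n = 3), a log2 fold change of -1.03 ± 0.22 (SE). The gene hsd3b1.L, a 3-beta-hydroxysteroid dehydrogenase, stood at 25.7 ± 3.31 and 42.8 ± 5.01 FPKM, a log2 fold change of -0.72 ± 0.14 (SE). The list as a whole was not called, with an adjusted p of 0.158 with camera, and its median log2 fold change was -0.0048. It was called lower without atrazine replicate 2 (adjusted p of 0.0171) and without control replicate 2 (adjusted p of 0.0221), but not with an estimated inter-gene correlation (adjusted p of 0.679) or with v10.1 symbols, where 57 rows had a median of 0.015 and an adjusted p of 0.184. Within the list prlr.S, a prolactin receptor gene, had a log2 fold change of 0.40 and akr1c3.L, a keto-steroid reductase gene, of -0.58.

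A further 4 rows of the same kind lay outside the list, as the deposited table named them only by a LOC number. They lay outside it with v10.1 symbols too, and were singled out after their values were seen. The insulin-like 3 row LOC108703714, named rflcii.S in assembly v10.1, had the smallest p of all mRNAs, 4.6e-06, and an adjusted p of 0.110 with limma. Its FPKM was 118, 86.7 and 152 in the atrazine libraries and 424, 455 and 504 in the control libraries. The insulin-like 3 row on chromosome 1L at 108881310 to 108887464, LOC108713404 or rflcii.L in assembly v10.1, had 31.2, 56.9 and 43.2 FPKM against 130, 143 and 206 FPKM. A StAR-like row, LOC108695784, had a log2 fold change of -1.04 and an adrenodoxin-like row, LOC100498263.L, of -0.92, each with a limma adjusted p of 0.693. Without atrazine replicate 3 the row LOC108703714 passed with an adjusted p of 0.0440, and without control replicate 1 with 0.0457. The gene cyp17a1.L, which encodes the enzyme that makes androgen precursors, had means of 114 ± 42.8 FPKM in atrazine and 141 ± 14.2 FPKM in control (SD, n = 3). Ferredoxin, encoded by fdx1.L, had a log2 fold change of -0.023. Cholesterol synthesis and uptake, the supply of the pathway, had 9 rows higher and 17 lower, a median log2 fold change of -0.15 and a camera adjusted p of 0.0697, with ebp.L at -0.75 and lipa.L at -0.41. That list was called without atrazine replicate 1 (adjusted p of 0.000624) and without control replicate 2 (adjusted p of 2.4e-05), with the replicate number as a block (adjusted p of 0.0155) and with v10.1 symbols (adjusted p of 0.0429). It was not called with an estimated correlation, at an adjusted p of 0.679 with deposited and 0.702 with v10.1 symbols, and its median was -0.071 without control replicate 3 (adjusted p of 0.226), -0.074 without control replicate 1 (0.337), -0.086 without atrazine replicate 2 (0.169) and -0.099 without atrazine replicate 3 (0.260).

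**Figure D1:**
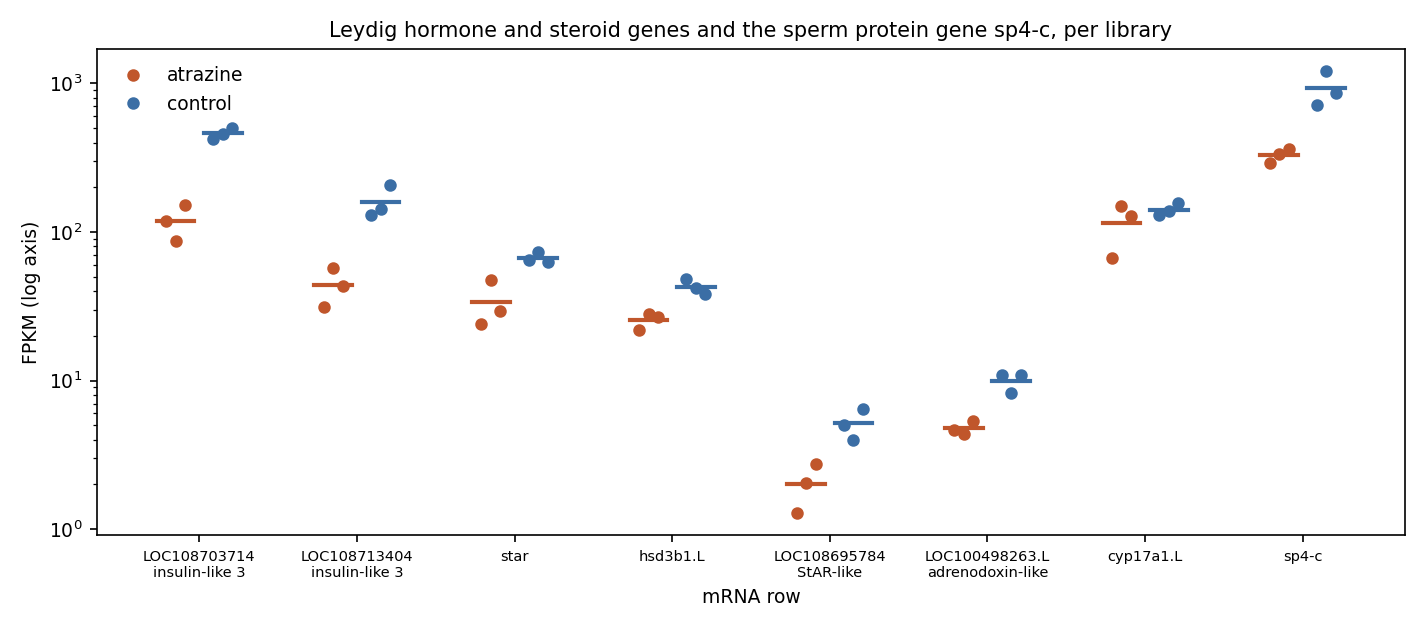
FPKM on a log axis of 6 Leydig hormone and steroid rows, of cyp17a1.L and of sp4-c, with 1 point per library (orange atrazine, blue control, 3 each) and a bar at the group mean. For LOC108703714 the atrazine libraries lay between 86.7 and 152 FPKM and the control libraries between 424 and 504, whereas the groups overlapped for cyp17a1.L.

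Germ cells at the end of spermatogenesis gave the most one-sided gene list. Of 55 measured rows for spermatids, the acrosome and the sperm flagellum, 47 were lower in atrazine, with a median log2 fold change of -0.34. Camera called the list lower with an adjusted p of 5.3e-12 at its preset inter-gene correlation of 0.01, but not with an estimated correlation, where the adjusted p was 0.624. None of its rows passed in limma, either over all genes or adjusted over the list alone. Among its members the cilium gene cfap52.S had means of 41.4 ± 8.89 FPKM in atrazine and 65.7 ± 20.03 FPKM in control (SD, n = 3), the intraflagellar transport gene ift74.L 23.0 ± 2.16 and 32.5 ± 7.58 FPKM, and the ciliary gene ccdc103 13.2 ± 3.25 and 19.2 ± 1.09 FPKM. Averaged over the list, log2(FPKM + 1) was 5.55, 5.15 and 5.56 in the atrazine libraries and 5.42, 5.94 and 5.84 in the control libraries, so control replicate 1 lay among the atrazine libraries and the exact permutation p was 0.3 (two-sided, smallest possible 0.1). Without atrazine replicate 2 the median log2 fold change was -0.20.

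Earlier germ cell stages gave no called list. Germ cell and spermatogonia genes had 12 rows higher and 6 lower and a median log2 fold change of 0.17 with a camera adjusted p of 0.228, with tdrd5.L, a piRNA pathway gene, at 0.49 and the stem cell factor receptor gene kit.L at 0.39. It was called higher without control replicate 1, with a median of 0.30 and an adjusted p of 0.0260, but its median was 0.052 without control replicate 2 (adjusted p of 0.850), and with an estimated correlation the adjusted p was 0.734. With v10.1 symbols the list had 32 rows in place of 18, a median of 0.16 and a camera adjusted p of 0.0549, just above the threshold, and 0.702 with an estimated correlation. Meiosis and synaptonemal complex genes had 6 rows higher and 6 lower, and sycp3.L, a core protein of the synaptonemal complex, had means of 110 ± 11.6 FPKM in atrazine and 125 ± 4.70 FPKM in control (SD, n = 3). The camera adjusted p of the meiosis list was 0.481. Its 12 rows covered only 10 symbols, and with v10.1 symbols 35 rows had a median of 0.062 against -0.028 (camera adjusted p of 0.973). Cell cycle genes had 37 rows higher and 45 lower with an adjusted p of 0.0833, among them cdk1.L at a log2 fold change of -0.44 and the kinetochore gene ndc80.L at -0.73. That list was called lower without atrazine replicate 1 (adjusted p of 0.0326) and without control replicate 1 (adjusted p of 0.0260), but not without atrazine replicate 3 (adjusted p of 0.260) or with an estimated correlation (adjusted p of 0.624).

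Genes of the ribosome and of the mitochondrial respiratory chain were called lower as groups by camera at its preset correlation, by small amounts and with libraries that overlapped between the groups. Of 97 ribosomal protein rows 75 were lower, with a median log2 fold change of -0.095 and a camera adjusted p of 8.4e-06, and with an estimated correlation the adjusted p was 0.679. Of 81 oxidative phosphorylation rows 59 were lower, with a median of -0.084 and a camera adjusted p of 0.000373, and with an estimated correlation the adjusted p was 0.624. None of the rows of either list passed in limma. Ribosomal rps29.S had means of 670 ± 17.04 FPKM in atrazine and 869 ± 60.9 FPKM in control (SD, n = 3), and the complex III gene uqcrq.S 416 ± 42.2 and 592 ± 106 FPKM. In the opposite direction ndufaf4.L, a complex I assembly factor gene, had means of 12.5 ± 6.20 and 3.41 ± 4.09 FPKM, with 0, 2.29 and 7.94 FPKM in the control libraries. That row lies at 1 to 183 and the uqcrq.S row (uqcrq.S_2) at 530 to 703 of unplaced sequences. Each may hold only a part of its gene. Without control replicate 3 the ribosomal median was -0.15, and with median-of-ratios scaling, which lowered other lists too, the oxidative phosphorylation median was -0.13. Averaged over the oxidative phosphorylation rows, log2(FPKM + 1) relative to the mean of all libraries was -0.0022, 0.031 and -0.12 in the atrazine libraries. It was -0.012, 0.036 and 0.065 in the control libraries, so the lower mean lay mostly in the shallow atrazine replicate 3. The ribosomal rows had 0.020, -0.029 and -0.12 against 0.11, 0.069 and -0.048. Glycolysis and the tricarboxylic acid cycle had 28 rows higher and 30 lower with an adjusted p of 0.160, and ldhb.S and pgk1.L had log2 fold changes of -0.45 and -0.35. The glycolysis list was called lower without atrazine replicate 1, with an adjusted p of 0.0338, but not without control replicate 1 (adjusted p of 0.850) or with an estimated correlation (0.734). Fatty acid metabolism had 16 rows higher and 22 lower with an adjusted p of 0.434, with gpam.S at 0.49 and acly.S at -0.31.

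Somatic cells of the testis were followed with marker lists, none of them called by camera. Sertoli cell genes had 12 rows higher and 22 lower (adjusted p of 0.252), and the transferrin gene tf.S, also on the fat body and liver list, had means of 15.4 ± 2.66 FPKM in atrazine and 8.22 ± 2.04 FPKM in control (SD, n = 3). Hormone and growth factor receptors had 34 rows higher and 11 lower with a median of 0.13 and an adjusted p of 0.0939, with the activin receptor gene acvr2a.L at 0.37. Without atrazine replicate 1 the receptor list was called higher with an adjusted p of 0.0164, and without control replicate 2 with 0.0221. Its median was 0.072 without atrazine replicate 3 (adjusted p of 0.372), and with an estimated correlation the adjusted p was 0.642. Oocyte genes had 21 rows higher and 18 lower with a median of 0.0076 and an adjusted p of 0.568. The median was -0.029 without atrazine replicate 1 and 0.047 without atrazine replicate 2. Not all of these genes mark germ cells of ovarian type, as ybx2.S stood at 309 ± 61.7 FPKM in atrazine and 430 ± 70.0 FPKM in control testes (SD, n = 3). Within the list gdf1.L had a log2 fold change of 0.87 and zp4.S, an egg coat gene, of -0.80. Ovarian somatic cell genes had 8 rows higher and 4 lower (adjusted p of 0.434), with nr5a2.S at 0.26 and esr2.L at 0.25. Fibroblast and extracellular matrix genes had 25 rows higher and 18 lower (adjusted p of 0.620), with vim.L at -0.52. Blood vessel endothelium had 3 rows higher and 10 lower (adjusted p of 0.158), muscle 9 and 19 (adjusted p of 0.164) and kidney tubule 10 and 10 (adjusted p of 0.926). With v10.1 symbols the endothelium list had 29 rows and a median of -0.0089 (camera adjusted p of 0.966), against -0.11 with deposited symbols. Its tilt thus depended on which rows carried a symbol. In the muscle list the row deposited as cnn1.L (cnn2.L in assembly v10.1) passed adjusted over the list alone, with an adjusted p of 0.0205 in limma. The muscle gene actc1.L, in contrast, had a log2 fold change of -0.69.

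Blood cell lists were not called by camera in the reported fit. Red blood cell genes had 6 rows higher and 10 lower with a median of -0.13 and a camera adjusted p of 0.0739, and the globin gene hbg1.L had means of 145 ± 36.1 FPKM in atrazine and 359 ± 221 FPKM in control (SD, n = 3). Without control replicate 1, control replicate 3 or atrazine replicate 2 the red blood cell list was called lower, with adjusted p of 0.0260, 0.0175 and 0.0435, as it was without a filter on low values (0.0136) and with the replicate number as a block (0.0163), but not with control replicate 2 left out (0.380) or with an estimated correlation (0.624). Immune and macrophage genes had 18 rows higher and 23 lower with an adjusted p of 0.160, including mpo.L, the neutrophil peroxidase gene, at -1.04 and the chemokine receptor gene cxcr4.L at 0.44. That list was called lower without atrazine replicate 2 (adjusted p of 0.00966), but not without control replicate 1 (0.690) or with an estimated correlation (0.682). Fat body and liver genes had 6 rows higher and 13 lower with an adjusted p of 0.158, including vtn.L, encoding vitronectin, at -1.20. They were called lower without control replicate 1, with an adjusted p of 0.0181, but not without atrazine replicate 1 (0.400) or with an estimated correlation (0.624). The vtn.L row (vtn.L_2) lies at 22 to 296 of an unplaced sequence, with low means of 2.06 FPKM in atrazine and 5.70 FPKM in control.

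Stress and detoxification lists were not called either. Xenobiotic metabolism had 18 rows higher and 20 lower (adjusted p of 0.270), and its 4 rows at an unadjusted p under 0.05, nqo1.L, gsto2.L, mgst1.L and gstm1.L, had log2 fold changes of -0.52, -0.65, -0.55 and -0.34. Oxidative stress response had 21 rows higher and 25 lower (adjusted p of 0.481). There the glutathione reductase gene gsr.L had means of 15.2 ± 0.667 FPKM in atrazine and 8.84 ± 2.27 FPKM in control (SD, n = 3), while the peroxidase gene gpx8.L had 15.1 ± 3.22 and 9.49 ± 0.820 FPKM. Endoplasmic reticulum and heat stress had 22 rows higher and 22 lower (adjusted p of 0.620), with hsp70.L at -0.54 in a row at 3 to 630 of an unplaced sequence. Apoptosis and p53 response had 24 and 21 (adjusted p of 0.986), with bax.L at 0.26, and autophagy 19 and 16 (adjusted p of 0.880), with atg12.S at 0.36. DNA damage repair had 43 rows higher and 16 lower with a median of 0.12 and an adjusted p of 0.158. It was called higher without control replicate 1 (adjusted p of 0.0260) and without atrazine replicate 3 (adjusted p of 0.0475), but its median was 0.015 without control replicate 2 (adjusted p of 0.585), and with an estimated correlation the adjusted p was 0.734.

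**Figure D2:**
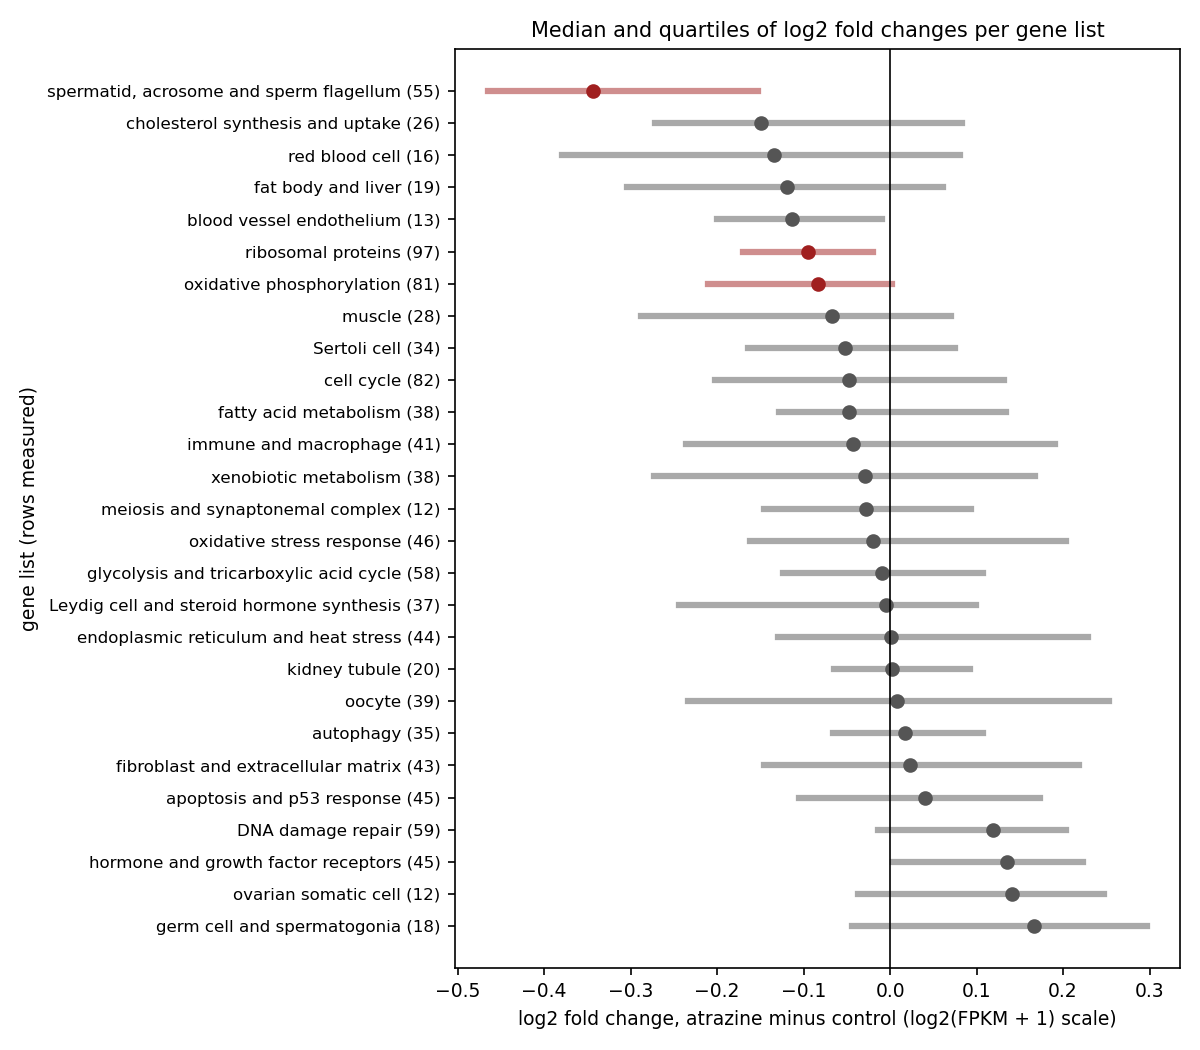
Median (point) and quartiles (bar) of the log2 fold changes of the measured rows in each of 27 gene lists, atrazine minus control on the log2(FPKM + 1) scale, with the number of rows in brackets. The 3 lists called by camera at its preset correlation are red, and the spermatid, acrosome and sperm flagellum list lies lowest with a median of -0.34.

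Genes of sex determination and steroid reception were named in advance. The androgen receptor gene ar.L had means of 5.65 ± 0.791 FPKM in atrazine and 4.62 ± 0.693 FPKM in control (SD, n = 3), a log2 fold change of 0.24. For the oestrogen receptor rows esr1.L and esr1.S the log2 fold changes were 0.088 and 0.086, for the testis transcription factor rows dmrt1.L and dmrt1.S 0.035 and -0.22, and for sox9.L and sox9.S -0.18 and 0.064. The sign of dmrt1.L flipped with median-of-ratios scaling, that of esr1.L with quantile normalization, that of esr1.S without control replicate 3, and that of sox9.S with library weights, without atrazine replicate 3 (-0.059) and without control replicate 1 (-0.18). Aromatase, which converts androgens to oestrogens and is encoded by cyp19a1.L, was near the floor in both groups, at 0.0328, 0.0931 and 0.258 FPKM in atrazine and 0.112, 0.0855 and 0.418 FPKM in control, and was not tested. The ovarian factor gene foxl2.S was also below the filter. The row LOC108719965, amh.L in assembly v10.1, which encodes anti-Müllerian hormone of Sertoli cells, had means of 18.7 ± 2.94 and 16.6 ± 1.33 FPKM. The row LOC108712986, cyp11a1.S in assembly v10.1, which encodes the first enzyme of steroid synthesis, had 1.35 ± 0.429 and 2.01 ± 0.212 FPKM. The limma adjusted p of these tested rows lay at or above 0.693.

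The second comparison concerned lncRNAs. Among those higher in atrazine the smallest p belonged to LOC108710739, a 132 nt intergenic transcript on chromosome 3L at 4472912 to 4481792, minus strand. Its FPKM was 2377, 1114 and 12432 in the atrazine libraries and 104, 102 and 155 in the control libraries, a log2 fold change of 4.75 ± 0.80 (SE), and its limma adjusted p was 0.248. LOC108716718, on chromosome 5L at 53775134 to 53780400, had means of 16.5 ± 1.73 FPKM in atrazine and 6.99 ± 1.68 FPKM in control (SD, n = 3). LOC108709086 on chromosome 2S was listed at 0 in all 3 atrazine libraries and at 1.89, 1.07 and 1.26 FPKM in the controls, and LOC108703115 on chromosome 9_10S was listed at 0 against 1.096, 0.782 and 0.942 FPKM. Their mean scaled signal over all libraries was only 0.589 and 1.04, so both contrasts rested on very few reads. With limma 0 of 1894 lncRNAs passed and 119 had an unadjusted p under 0.05, of which 65 were higher and 54 lower. Leaving out control replicate 1 gave 1 called lncRNA, XR_001934080, higher in atrazine by a log2 fold change of 5.37, and leaving out control replicate 2 gave 75 at an unadjusted p under 0.05.

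The third comparison concerned circRNAs. Fewer kinds were detected in atrazine testes, 13814 ± 2988 per library against 18547 ± 2589 in controls (SD, n = 3), with an exact permutation p of 0.2 (two-sided, smallest possible 0.1). The junction reads themselves were fewer, and relative to 1000000 reads of the mRNA table they numbered 4266 ± 831 in atrazine and 4545 ± 532 in control (SD, n = 3, exact permutation p of 0.6). Thinned to the smallest library the difference was -2593 circRNAs (exact permutation p of 0.1), and when at least 2 reads were asked of the thinned libraries, the minimum in the deposited table, it turned to 1064 more in atrazine (exact permutation p of 0.3). That step left the other libraries fewer reads than atrazine replicate 3, and with totals matched after it the difference was 119 more in atrazine (exact permutation p of 0.7). Of 68575 circRNAs, 53482 (78.0%) were seen in 1 library only and 1061 in all 6. Most were exonic, 53228 in number.

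**Figure D3:**
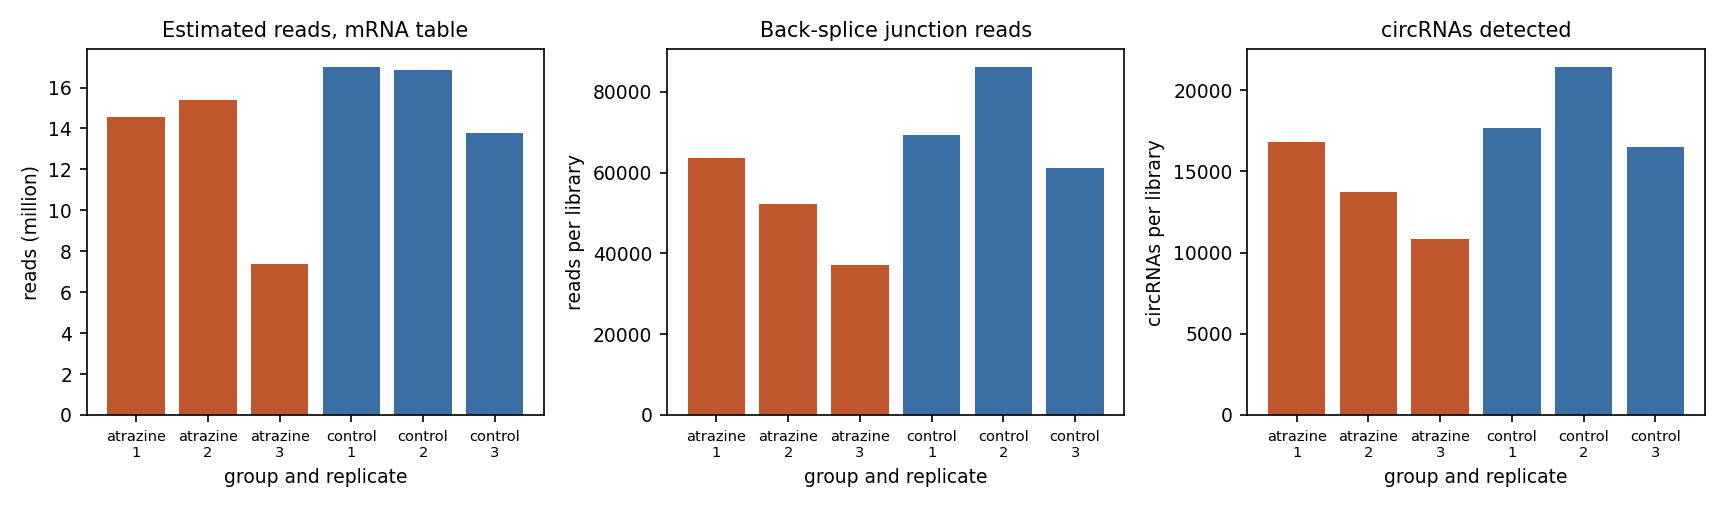
Estimated reads of the mRNA table, back-splice junction reads and circRNAs detected, 1 bar per library (orange atrazine, blue control). Atrazine replicate 3 had the fewest of each, at 7360619 reads, 37092 junction reads and 10857 circRNAs.

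No single circRNA passed in the edgeR quasi-likelihood test, with 0 of 6592 called, and DESeq2 also called 0. At an unadjusted p under 0.05 edgeR gave 408, of which 81 were higher and 327 lower, and DESeq2 gave 119, of which 67 were lower. The tested circRNAs had a median of 2.33 reads per library, and their median log2 fold change was -0.25 with TMM scaling and -0.054 with library totals. The lower ones with the smallest p were exonic rings of ccdc6.S (chromosome 7S, 8180908 to 8181978), ttll7.L (4L, 67190695 to 67207690) and mtf2.S (4S, 77496813 to 77500806), host genes of a coiled-coil protein, a tubulin glutamylase and a chromatin reader. They were listed at 0 in all atrazine libraries and at 13, 11 and 11, at 9, 15 and 10, and at 14, 9 and 8 junction reads in the control libraries. The higher ones came from LOC108707857 (2L, 10969852 to 10971839), LOC108698445 (8L, 39776310 to 39778799) and LOC108717113 (5L, 125649603 to 125650002). The ring of LOC108707857 had 15, 5 and 17 reads in atrazine against 0, 2 and 2 in control, that of LOC108698445 had 10, 7 and 4 reads and that of LOC108717113 had 5, 7 and 5 reads, the last 2 against 0 in every control library. All of them had an edgeR adjusted p of 0.640. Leaving out a control library gave 2 called circRNAs without replicate 1, 1 without replicate 2 and 2 without replicate 3. Each library left out lowered the number at an unadjusted p under 0.05, to 292 without atrazine replicate 1, 149 and 146 without atrazine replicates 2 and 3, and 73, 68 and 70 without control replicates 1, 2 and 3, and without control replicates 1 or 2 the higher ones outnumbered the lower (39 to 34 and 38 to 30). The filter still asked for 3 libraries in these fits. Without a control library it removed the 287 circRNAs seen in all 3 control libraries and no atrazine library, but kept the reverse 76. The fall and the turn are thus set at least in part by the filter, and do not show whether the excess of lower ones is stable.

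Whether circRNAs moved with the mRNAs of their host genes was examined over 6035 pairs. Spearman's correlation of the log2 fold changes across circRNAs was 0.035, and circRNAs of one gene are not independent replicates. Among the 300 pairs whose circRNA was lower at an unadjusted p under 0.05 the host mRNA was lower in 155, with a median host log2 fold change of -0.0038, and among the 78 pairs whose circRNA was higher it was lower in 32, with a median of 0.043. Limited to circRNAs with at least 5 reads in 3 libraries the correlation was 0.11, over 1665 pairs, and without control replicate 1 it was 0.081.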

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

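The counts of called RNAs stayed at 0 under most settings. Depth limits how many circRNAs can be tested, 6592 with all reads and 3678 on average once thinned to 37092 reads per library. Settings named here as added were chosen after the data were seen. Called mRNAs numbered 0 in the reported fit, 52 at an unadjusted p under 0.05 with a 2-fold change (14 higher, 38 lower), and 0 to 5 with a library left out. Among the added settings, library weights gave 5, in a fit of weights that stopped before it converged and gave control replicate 3 a weight of 6.74, and the scaled signal in place of FPKM gave 1. LOC108703714 was among the calls under every one of these settings that gave any. Called lncRNAs numbered 36 at the unadjusted threshold with a 2-fold change and 0 to 1 with a library left out. Called circRNAs numbered 404 at that threshold, 3 without a filter and 0 to 2 with a library left out, and limma on the deposited log2 values, an added setting, gave 4. The 3 without a filter each had all of their reads in 1 or 2 atrazine libraries. Same-numbered libraries did not deviate together, with correlations of 0.0254, -0.35 and -0.0389, so the numbers were not taken to pair samples. With the replicate number as a replicate block 0 mRNAs, 0 lncRNAs, 1 circRNA and 5 gene lists (cholesterol and red blood cell genes too) were called, and the circRNA-host correlation was 0.033. Called gene lists numbered 3 in the reported fit, 0 with an estimated correlation, 0 with fry, 4 without a filter (red blood cell genes too), 4 with v10.1 symbols, an added setting (cholesterol too), and 4 to 8 with a library left out. The difference in detected circRNAs, -4733, did not move with a minimum of 2 reads, since no count was 1, ranged from -6243 to -3255 with a library left out, and reversed to 1064 with thinned reads and at least 2 of them and to 119 with totals matched after that minimum, both added settings. The circRNA-host correlation was 0.11 with at least 5 reads and 0.034 to 0.081 with a library left out. Under alternatives 7 of 456 values of named RNAs passed the threshold newly and the others kept their side, and of 351 values of the 27 gene lists 21 passed it newly, 17 of them with a library left out, and 6 no longer did, being the 3 called lists with an estimated correlation and with fry. Of 456 fold changes of named RNAs 6 changed sign, all of dmrt1.L, esr1.L, esr1.S or sox9.S. The pseudocount alternative for circRNAs was not run, as counts were tested. The cause of these differences was not tested, except where fewer libraries or rows entered.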

Other observations

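The tests weighed here were chosen after the results were seen, except the counts of lncRNAs, circRNAs and gene lists over other splits of the libraries. The lncRNA LOC108710739, which had the highest fold change of the named lncRNAs, also overlapped a circRNA that was not tested because it was detected in 2 libraries. That ring spanned 4438754 to 4473790 on chromosome 3L, on the same strand, and ended inside the lncRNA gene. It had 140, 0 and 450 junction reads in atrazine replicates 1, 2 and 3 and 0 in all 3 control libraries, and the scaled signal of the lncRNA was 180, 77.3 and 970 against 8.32, 5.89 and 10.3. Both tables come from the same libraries, so they are not independent measurements.

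Fold changes of L and S copies of a gene were correlated, which reads shared between the copies could also give. Over 618 pairs with both copies tested Spearman's correlation of their log2 fold changes was 0.44, and 70.7% of pairs had the same sign. The other 9 splits of the 6 libraries gave 0.164 to 0.436, all below the 0.439 of the real one, though the highest was nearly equal to it. With 10 splits no share under 0.05 can be reached, and the splits do not address shared reads. In 6 of the 7 pairs in which both copies had an unadjusted p under 0.05 the copies had the same sign. They included dbi, encoding the acyl-CoA binding protein, at -0.37 and -0.46, and dtl, a replication licensing gene, at 0.37 and 0.44.

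Among Leydig hormone and steroid genes 6 rows picked for being lower in atrazine (both insulin-like 3 rows, star, hsd3b1.L, StAR-like and adrenodoxin-like) had a median log2 fold change of -1.03, while the whole list of 37 rows, fixed beforehand, had 18 higher and 19 lower and was not called (adjusted p of 0.158, and 0.184 with v10.1 symbols; 0.0171 without atrazine replicate 2 and 0.0221 without control replicate 2). Without the shallow library of atrazine replicate 3 the 6 rows had a median of -1.10. As they were picked for being lower in atrazine, this shows only that these rows did not rest on that library. The summed FPKM of both insulin-like 3 rows was 3.82-fold higher in control (163 ± 27.9 in atrazine against 621 ± 80.1 FPKM, SD, n = 3, exact permutation p of 0.1). Both rows were picked as lower, so their sum had to be lower too and is no test of reads passing between the L and S copies. A loss of Leydig cells, which would lower all their genes alike, was set against cyp17a1.L, and cannot be told apart from lower expression per cell. The gene was less lowered than the 6 rows by 1.12 (hsd3b1.L) to 8.14 standard errors, by more than 2 for 4 of them, but these rows had been picked for being low and its own log2 fold change ran from -0.61 without atrazine replicate 2 to -0.032 without atrazine replicate 1, and LOC108712986 (cyp11a1.S), less lowered than all 6 by 2.22 to 7.42 standard errors, is a low row that at a pseudocount of 0.1 lay within 0.628 standard errors of hsd3b1.L. An effect of the exposure and other differences between the 6 libraries stay open, untested.

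Lower spermatid, acrosome and sperm flagellum genes may reflect testes that differ in how many late germ cells they hold, whatever the exposure. The groups' list means differed by 1.21 pooled standard deviations of the libraries. Control replicate 2, the highest for this list, was also the highest for the red blood cell, muscle and blood vessel lists, so the libraries differed in more than late germ cells. The shallow atrazine library is argued against by a median log2 fold change of -0.41 without it. A lasting effect of atrazine on late germ cells stays open as well.

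For each circRNA higher in atrazine at an unadjusted p under 0.05 there were 4.04 lower ones in edgeR but 1.29 in DESeq2 (67 lower, 52 higher), and in edgeR the higher ones outnumbered the lower without control replicate 1 (39 to 34) and without control replicate 2 (38 to 30). Those 2 fits cannot weigh the excess, as the filter on 3 libraries left circRNAs seen only in the control libraries untested there. Whether the smaller junction read totals of the atrazine libraries account for all of the excess in edgeR stays open, as the thinnings fell on both sides of the bound of 1.5. With every library thinned to the 37092 reads of atrazine replicate 3, which itself was not thinned, the ratio was 1.53 on average over 20 draws (1.16 to 2.13 in single draws), although this keeps single reads that the deposited table lacks. With single reads set to 0 after thinning it was 1.01 (0.725 to 1.19), although this leaves the other libraries fewer reads, and with totals matched after that step it was 1.45 (1.13 to 1.75). circRNAs seen in all 3 control libraries and no atrazine library numbered 287 and the reverse 76, while atrazine replicate 1 with control replicates 1 and 2, the 3 libraries with the most junction reads, had 321 that the others lacked, and after these thinnings, in the same order, the control and atrazine libraries had 204 and 84.5, 82.2 and 82.6, and 113 and 79.3 on average. An effect of the exposure on circRNAs stays open, untested.

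With 10 splits of the 6 libraries no share under 0.05 can be reached. With 0 RNAs called in the real split, all 10 splits give at least as many whatever the data, so that count says nothing about mRNAs (highest other 3), lncRNAs (highest other 4) or circRNAs (highest other 2). At least as many called lists came from 9 of the 10 splits, the real one included (3 called, highest other 7), and 1 other split gave fewer. Of the 9 other splits 7 gave fewer mRNAs at an unadjusted p under 0.05 than the 1410 of the real one (180 to 1089) and 2 gave more, 2356 and 4844. The last, of atrazine replicates 1 and 2 with control replicate 1 against the rest, points to a structure of the samples other than their group.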
